A study of Homo sapiens with 20 samples.

How the data were processed

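The series held 20 arrays hybridised with RNA of 4 ABC DLBCL cell lines, 16 from a birinapant time course and 4 from an inducible knockdown of cIAP1 and cIAP2. According to the file headers and the submitters' processing notes, the arrays were read with Agilent Feature Extraction 10.1.1.1, and the knockdown arrays were of another Agilent design than the birinapant arrays. Per the file headers, the mean signal and local background of each spot in either channel are an intensity before background subtraction. The processed signals are also an intensity, which the authors' Feature Extraction subtracted for background, detrended and normalised between the dyes. The deposited LogRatio is the log10 of the processed Cy5 over Cy3 signal, set to 0 for 0.838% to 37.6% of the spots of an array. The deposited table of values is also log10 of Cy5 over Cy3, with a slope of 0.989 to 1.01 against LogRatio and r of 0.861 to 1.00. Its column medians at 2, 4, 6 and 24 h were 0, 0.0045, -0.002 and -0.003 in HBL1, -0.074, 0.017, 0.02 and -0.044 in TMD8, -0.076, -0.04, -0.041 and -0.046 in OCILY3, and -0.057, -0.045, -0.055 and -0.01 in OCILY10. The medians of the knockdown columns were -0.056 and -0.046 for TMD8 and -0.031 and -0.009 for HBL1 at 3 and 4 days. How the authors centred or scaled that table was not stated and stays unknown, and its direction, treated over control, was read from its match to LogRatio.

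Mean signals were background corrected with normexp (offset 50), turned into log2 ratios of Cy5 over Cy3 and normalised within each array by loess, with limma 3.58.1 in R 4.3.3, data.table (version 1.17.8), and Python 3.11.15 with matplotlib 3.10.9 for the plots. A probe was kept when it was well above background in either channel on at least 4 of the 16 birinapant arrays or 2 of the 4 knockdown arrays, per the flags in the files. Each gene was represented by its kept probe of highest mean intensity. On the birinapant arrays 32456 of 50599 probes were kept for 24437 genes, 16395 of them with a symbol, and on the knockdown arrays 26572 of 42405 probes for 20751 genes, 14890 with a symbol. Gene symbols came from accessions where these matched the reference and otherwise from the array design, which places probes on the hg19 build. Spots marked non-uniform in either channel were left out, and 1545 probe values were missing on the birinapant arrays and 24 on the knockdown arrays. Saturated spots were kept.

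Ratios were tested against 0 at each time and in the knockdown, without a block, by limma's lmFit and eBayes. P-values had Benjamini-Hochberg adjustment over all genes of the array design, with a threshold of 0.05. The birinapant times were fitted together, so the SE and p at a single time rest on a residual spread pooled over all times. The SD and n printed there are of that time's arrays alone. Without a block, this fit treats the arrays of a line as independent, although they could share a DMSO sample. Contrasts of 24 h or 6 h with 2 h had the cell line as a fixed block. The mean over 4 times and the contrast of OCILY3 with the other 3 lines used line means (n = 4 lines), and differences among the 4 lines had an F-test with time as a block. The 34 gene lists, these comparisons and the alternatives were chosen before the data were examined. Some lists share genes, so the calls of such lists are not independent. The lists at single times, between 2 and 6 h and between 6 and 24 h, the contrast of 24 h with 6 h, the ribosomal group, the runs without the 3 bright arrays and the list tests with the block exchanged were added afterwards. Lists were tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry, adjusted over the lists, and their genes were also adjusted over the list alone.

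Genes are named by a rule that always takes BIRC2, BIRC3 and XIAP. In each comparison it adds the 10 largest increases and the 10 largest decreases among genes past the threshold with a symbol, the same sign in every array or line, and a probe well above background in at least 1 channel on every array. Where fewer than 5 genes passed in a direction, the 5 largest were taken without regard to the threshold, and up to 4 members of each list with the smallest p were added. A few genes that the rule takes are not printed. For the contrasts of OCILY3 the SD is not given because its 3 differences share 1 line.

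The replicate numbers of the labels stand for cell lines, so arrays of a line were taken as paired. The median correlation of a line's deviations from the time means was -0.036 in HBL1, -0.029 in TMD8, 0.11 in OCILY3 and 0.062 in OCILY10. The Cy3 channels of a line correlated at 0.982 to 0.996 and those of different lines at 0.889 to 0.944, without the 3 bright arrays. The arrays of a line could therefore share a DMSO sample. If so, the spread between DMSO samples of 1 line was not measured. An error of a line's control then enters the tests against DMSO through the spread between lines. It cancels in contrasts of times within a line. The birinapant arrays filled 2 slides, HBL1 and TMD8 on one and OCILY3 and OCILY10 on the other, with time following the column of the slide, so time and column cannot be told apart. In simulated data with 200 changed genes, a log2 change of 1 was found in 97%, 100%, 97% and 100% of cases at 2, 4, 6 and 24 h, 100% for the mean, 83% between 2 and 24 h, 87% between 2 and 6 h, 82% for OCILY3 and 89% in the knockdown, and a change of 0.5 in 70%, 79%, 75%, 77%, 94%, 34%, 43%, 0% and 61%. Between 1 and 15 unchanged genes were called per comparison. The simulated noise was independent between genes and arrays, and a change was equal on all arrays concerned. It held no shared DMSO sample, no bias of single arrays and no change that differs between lines. The shares found can therefore be too high for the real data.

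Alternatives were the deposited LogRatio, the deposited value table, no background correction, median centring without loess, Aquantile, no filter or a stricter filter, the mean of all probes of a gene, other blocks for line or slide, single slides, the arrays of a time alone, an intensity trend with robust eBayes, and leaving out each line or knockdown array in turn. No dye-swapped array existed, so dye bias was not removed. Control spots were left out, and count-based tools do not apply to intensities.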

Results

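Gene expression was measured in 4 human cell lines, HBL1, TMD8, OCILY3 and OCILY10, all models of activated B-cell-like diffuse large B-cell lymphoma (ABC DLBCL), a lymphoma that depends on NF-kB signalling. Each of 20 Agilent arrays compared treated cells, labelled with Cy5, with control cells of the same line, labelled with Cy3, and every value below is a log2 ratio of Cy5 over Cy3. On 16 arrays the treated cells had received 2.5 µM birinapant for 2, 4, 6 or 24 h and the control cells DMSO, with 1 array per line and time (n = 4 lines per time). Birinapant is a SMAC mimetic, a small molecule that binds inhibitor of apoptosis proteins and triggers the degradation of cIAP1 (gene BIRC2) and cIAP2 (gene BIRC3). On the other 4 arrays, TMD8 and HBL1 cells expressing a doxycycline-induced hairpin pair against cIAP1 and cIAP2 for 3 or 4 days were compared with cells expressing a control hairpin (n = 4 arrays from 2 lines). On 13 of the birinapant arrays between 35.3% and 47.7% of probes were well above background in a channel. On the 3 bright arrays (HBL1 at 2 h, HBL1 at 4 h and TMD8 at 6 h) the share was between 69.8% and 95.6%, and on the knockdown arrays between 50.6% and 62.8%. The small number of arrays limits the precision of every value. The labels do not say whether arrays of a line came from separate cultures, nor for how long the DMSO cells were kept. The p-values therefore measure the spread between these samples. At a single time of birinapant that spread is pooled over the arrays of all times, not taken from the n = 4 lines of that time alone. No array had the dyes exchanged, so a ratio of treated over control carries any bias of the dyes. A bias that is the same on every array cancels in contrasts between times or lines, but a bias of single arrays does not. The log2 ratios of HBL1 at 2 h and at 4 h, both bright arrays, correlated at 0.606. Those of the bright TMD8 array at 6 h correlated with them at 0.51 and 0.669, against 0.097 with TMD8 at 4 h.

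The hairpins asked what loss of both proteins does without a drug, and their target genes were examined first. BIRC2 fell by 1.96 on the log2 scale (SE 0.157, SD 0.456, n = 4 arrays, adjusted p = 0.00519), with values of -1.45 and -1.72 in TMD8 at 3 and 4 days and -2.26 and -2.43 in HBL1. BIRC3 fell by 1.62 (SE 0.122, SD 0.342, adjusted p = 0.00519), with -1.16 and -1.61 in TMD8 and -1.72 and -1.98 in HBL1. XIAP, a related inhibitor of caspases that the hairpins do not target, had 0.14 (SD 0.076, adjusted p = 0.208). The probes lie on the GRCh37 (hg19) build at 102248391 to 102248450 of chromosome 11 for BIRC2, 102208356 to 102208415 of chromosome 11 for BIRC3 and 123047703 to 123047762 of chromosome X for XIAP. No gene annotation of that build was at hand, so the exon or UTR under each probe is not given. With birinapant no time point gave a call for the transcripts of the 3 genes. BIRC3, itself an NF-kB target, had means of 0.032, -0.46, -0.33 and 0.46 at 2, 4, 6 and 24 h (SD 0.128, 0.411, 0.501 and 0.319, n = 4 lines, adjusted p = 0.944, 0.285, 0.478 and 0.309). Its 24 h values were 0.70 in HBL1, 0.75 in TMD8, 0.087 in OCILY3 and 0.31 in OCILY10. BIRC2 had means of 0.068, -0.17, -0.13 and 0.025 (adjusted p = 0.774, 0.67, 0.685 and 0.981), and XIAP 0.092, 0.027, -0.14 and -0.070 (adjusted p = 0.765, 0.984, 0.754 and 0.939). The negative XIAP means rest on TMD8, at -0.90 on the bright 6 h array and -0.51 at 24 h, and without TMD8 they were 0.116 and 0.077.

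**Figure D1:**
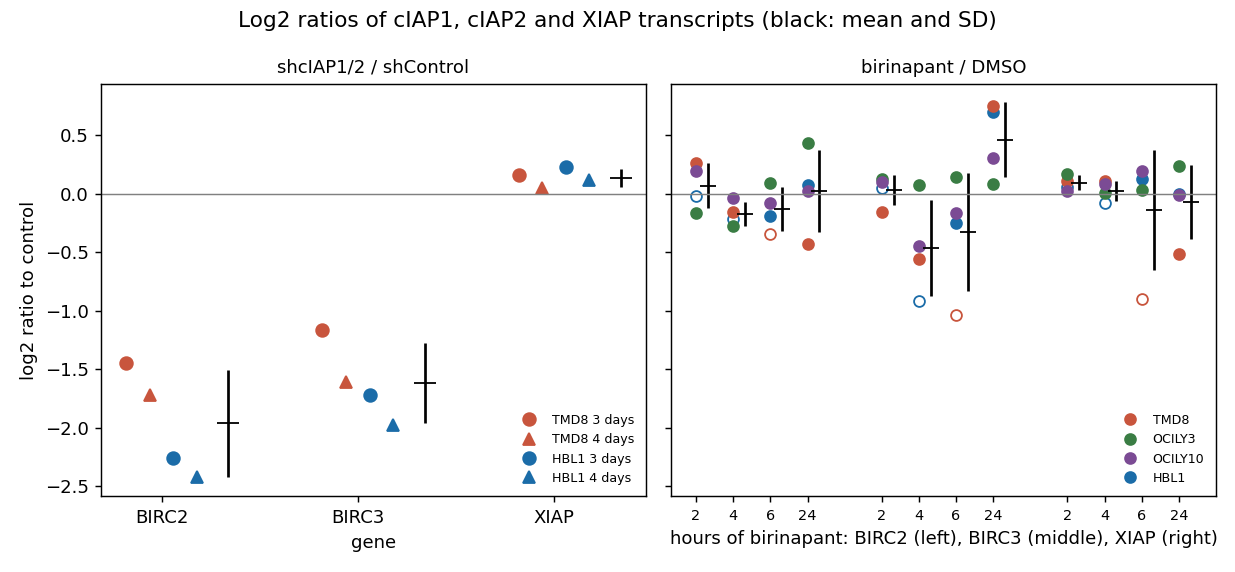
Log2 ratio of Cy5 over Cy3 of BIRC2, BIRC3 and XIAP on each array (vertical axis) by time of birinapant or day of knockdown (horizontal axis, not to scale), with coloured symbols for the cell lines offset sideways, open symbols for the 3 bright arrays, and the mean and SD in black. BIRC2 lies between -2.43 and -1.45 on the 4 knockdown arrays, and the birinapant values of BIRC3 at 24 h lie between 0.087 and 0.75.

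With cIAP1 and cIAP2 knocked down, most genes of the glycolysis list were below the control. PGAM1, the phosphoglycerate mutase of glycolysis, fell by 1.07 (SD 0.124, adjusted p = 0.00451), and its near-identical copy PGAM4 by 0.99. HILPDA, a hypoxia-induced lipid droplet protein, fell by 1.24 (SD 0.699, adjusted p = 0.0356). PFKFB4, a regulator of glycolytic flux, fell by 0.68 (SD 0.126, adjusted p = 0.00742) and LDHA, lactate dehydrogenase, by 0.43 (SD 0.07, adjusted p = 0.013). Of 31 glycolysis and hypoxia genes 27 were negative, 12 were called lower over all genes and 20 when adjusted over the list alone (median -0.26, adjusted p = 5.09e-11, and adjusted p = 0.163 with an estimated correlation). Lower genes of B cell function were JCHAIN, which joins antibody subunits (-0.96, SD 0.36, adjusted p = 0.0145) and MZB1, an antibody chaperone (-0.63, adjusted p = 0.012). Also lower was ICAM1, an adhesion molecule induced by NF-kB (-0.82, SD 0.237, adjusted p = 0.00996). Higher genes were MSMO1, a sterol demethylase (1.21, SD 0.25, adjusted p = 0.00519), and TXNIP, an inhibitor of thioredoxin (0.97, SD 0.573, adjusted p = 0.0412). TIAM1, an activator of Rac, was higher as well (0.85, SD 0.282), as was RPL13A, a ribosomal protein (0.91, SD 0.089, adjusted p = 0.00494). Ribosomal protein genes read as high on the birinapant arrays, which had the same dye order (mean of array medians 0.405 against 0.389 here). For these genes a dye bias cannot be told apart from an effect of the knockdown. Other genes named by the rule were ADIRF (1.16), GNG8 (0.91), GPR18 (0.88), RPS2 (0.87) and TUBB3 (0.83) among the higher. Among the lower were the phosphatases DUSP5 (-0.97) and DUSP26 (-0.93), the cell cycle factor E2F2 (-0.94) and WNT10A (-0.92).

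In all, limma called 940 of 20751 genes in the knockdown, 598 higher and 342 lower (adjusted p below 0.05, n = 4 arrays). With the cell line as a block, which takes the difference between the lines out of the spread, 2726 genes were called. A random line effect gave 589 and the mean of each line 0 (2736 at an unadjusted p below 0.05). Leaving out the HBL1 array at 3 days gave 0 calls (3451 at an unadjusted p below 0.05), the HBL1 array at 4 days 37, the TMD8 array at 4 days 246 and the TMD8 array at 3 days 586. The LogRatio deposited by the authors gave 103.

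Among the 34 gene lists, camera with a preset correlation called 10 in the knockdown, and none of the 10 held with an estimated correlation. Plasma cell genes were lower in 13 of 15 (median -0.33, adjusted p = 4.75e-07), with adjusted p = 0.163 with an estimated correlation. Of them 6 were called lower, and 12 when adjusted over the list alone. MHC class II genes, which present antigen, were lower in 14 of 15 (median -0.37, adjusted p = 8.88e-07, and 0.505 with an estimated correlation). HLA-DMA (-0.44) and HLA-DRB1 (-0.47) were called lower, and 9 genes when adjusted over the list alone. Canonical NF-kB targets were lower in 28 of 39 (median -0.16, adjusted p = 0.000149, and 0.481 with an estimated correlation). Of these 4 were called lower, 9 over the list alone, the 4 being BIRC3, which a hairpin targets, ICAM1, NFKB1 (-0.43) and the survival gene BCL2L1 (-0.24). ABC subtype genes were negative in 24 of 29 (median -0.14, adjusted p = 0.000238, and 0.46 with an estimated correlation). Of these 5 were called lower, among them the kinase PIM1 (-0.37), and 10 lower and 1 higher when adjusted over the list alone. MYC targets and ribosome biogenesis genes were positive in 36 of 40 (median 0.11, adjusted p = 0.000304, and 0.199 with an estimated correlation). The 3 called were NPM1 (0.51, with another probe at -0.16), GNL3 (0.26) and NOP2 (0.26). The unfolded protein response was negative in 16 of 23 (median -0.17, adjusted p = 0.0025, and 0.46 with an estimated correlation). HSP90B1 (-0.34) and PDIA4 (-0.29) were called lower, and 7 over the list alone. The G2/M list had no called gene and 34 of 39 negative (median -0.10, adjusted p = 0.00184, and 0.78 with an estimated correlation). Its medians were -0.005 and 0.13 in TMD8 and -0.12 and -0.35 in HBL1. The list of IAPs and their antagonists had 7 of 10 negative with BIRC2 and BIRC3 called (median -0.21, adjusted p = 0.00772, and 0.46 with an estimated correlation). Both called genes are targets of the hairpins, so a downward call of this list was made likely by the design. The mature B cell list had 17 of 24 negative with CD52 (-0.56) called (median -0.12, adjusted p = 0.0333, and 0.46 with an estimated correlation). With the LogRatio deposited by the authors 9 of the 10 were still called, the mature B cell list being lost (adjusted p = 0.0823).

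The remaining 24 lists were not called in the knockdown. With the cell line as a block 12 lists were called, with the type I interferon list (adjusted p = 0.014) and the T and NK cell markers (adjusted p = 0.0483) added. The spread in that fit is between the days of a line, not between the lines. The interferon list had a median of 0.12 (adjusted p = 0.111), with medians of 0.29 and 0.29 on the TMD8 arrays and 0.012 and -0.059 on the HBL1 arrays. IFIT5 (0.62), IFIT2 (0.40) and IRF9 (0.39, another probe -0.079) were called higher. T and NK cell markers, a list of other cell types, had a median of -0.050 (adjusted p = 0.116) with GZMB (-0.47) called, and myeloid markers -0.005 (adjusted p = 0.93). GZMB was also well above background on 8 of 8 birinapant arrays at 2 and 24 h, so these lines do not lack every gene of that list. B cell receptor signalling had -0.038 (adjusted p = 0.116), with BLNK (-0.41), CD79B (-0.34) and BTK (-0.31) among those called lower. The p53 list had 0.11 (adjusted p = 0.125), with TIGAR (0.51), TNFRSF10B (0.42), TRIAP1 (0.32) and FBXO22 (0.29, another probe -0.003) called higher. The non-canonical NF-kB list had -0.089 (adjusted p = 0.116), with the hairpin targets BIRC2 and BIRC3 called. MAP3K14, which encodes the kinase NIK, stood at 0.37 (adjusted p = 0.0833) and NFKB2 at -0.23 (adjusted p = 0.101). These are transcripts, whereas cIAP1 and cIAP2 keep NIK low as a protein, which the arrays do not measure. The heat shock list had 0.22 (adjusted p = 0.14), with 1.25 on the TMD8 array at 3 days and -0.43, 0.11 and 0.15 on the other 3 arrays. That TMD8 array also went against the other 3 in lists whose pooled medians, given below, were small. It had -0.207 against 0.142 to 0.177 in the integrated stress response. Its chemokine median was 0.296 against -0.035 to -0.009, and its immediate early median 0.313 against -0.17 to -0.096. Medians and adjusted p were -0.062 and 0.154 for JAK-STAT3, -0.094 and 0.154 for Toll-like receptor genes, 0.053 and 0.154 for the integrated stress response. Likewise they were -0.036 and 0.193 for germinal centre genes, and -0.069 and 0.208 for the TNF superfamily. They were -0.058 and 0.358 for pro-survival genes, -0.004 and 0.399 for NRF2 targets, -0.025 and 0.539 for G1/S, -0.001 and 0.645 for the proteasome. Pro-death genes had 0.021 and 0.668, and there RIPK1 (0.30) and CASP8 (-0.29) went opposite ways. They were 0.018 and 0.69 for MHC class I, 0.079 and 0.791 for chemokines, 0.036 and 0.791 for reference genes, and -0.014 and 0.969 for immediate early genes. The ubiquitin list had a median of 0.039 but a mean of -0.14 and a downward test (adjusted p = 0.668). Cholesterol biosynthesis had a median of -0.015 but a mean of 0.034 (adjusted p = 0.93), and oxidative phosphorylation had a median of -0.003 but a mean of 0.007 and an upward test (adjusted p = 0.939).

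**Figure D2:**
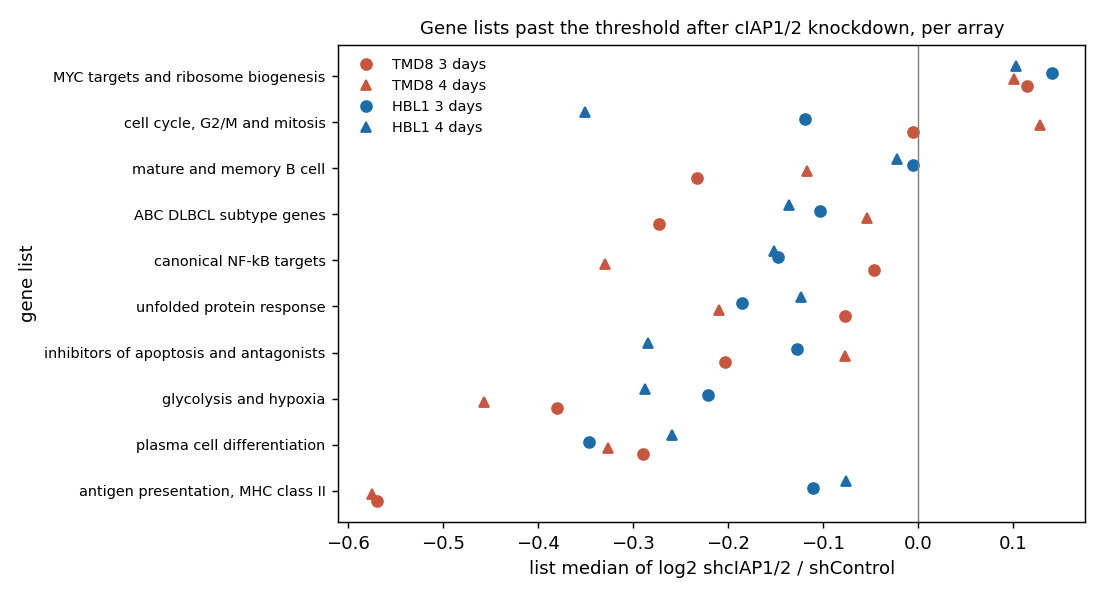
Median log2 ratio (horizontal axis) of each of the 10 gene lists called in the knockdown, on each of the 4 knockdown arrays, with a symbol for each line and day. MHC class II lies at -0.57 and -0.58 on the TMD8 arrays and at -0.11 and -0.076 on the HBL1 arrays.

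The time course asked how transcripts move while birinapant acts, and the NF-kB targets were below DMSO at 4 and 6 h and above it at 24 h in HBL1, TMD8 and OCILY10. Their medians over the 40 genes at 2, 4, 6 and 24 h were 0.051, -0.33, -0.33 and 0.12 in HBL1 and 0.20, -0.14, -0.16 and 0.63 in TMD8. They were -0.010, -0.40, -0.75 and 0.23 in OCILY10, and 0.029, -0.001, 0.072 and 0.14 in OCILY3.

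**Figure D3:**
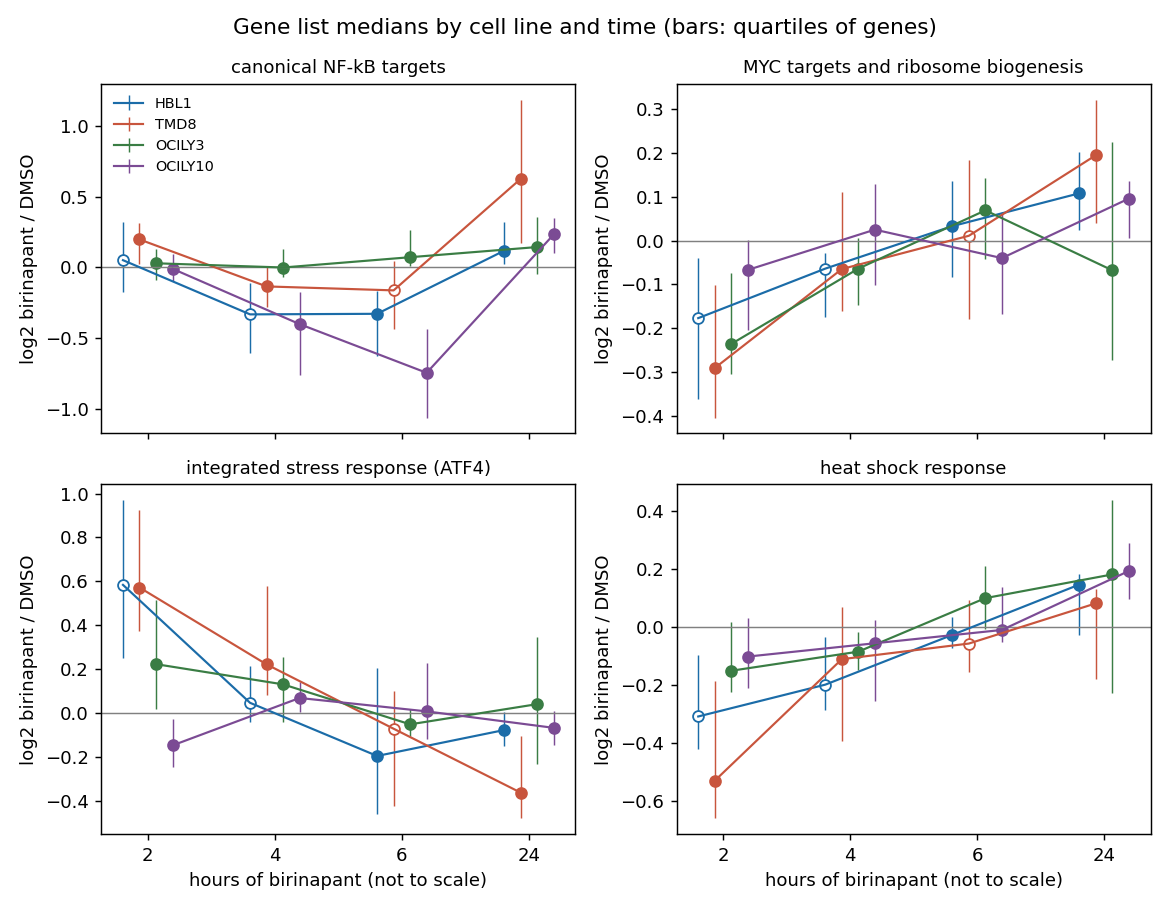
Median log2 ratio of Cy5 over Cy3 of selected gene lists (vertical axis) on each birinapant array by time (horizontal axis, not to scale), with a colour for each line, symbols offset sideways, open symbols for the 3 bright arrays and error bars for the quartiles of the genes. The NF-kB targets lie between -0.75 and 0.072 at 6 h and between 0.12 and 0.63 at 24 h.

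At 2 h of birinapant, the integrated stress response list was called higher and the heat shock and cholesterol lists lower, none of which held with an estimated correlation (adjusted p = 0.503, 0.141 and 0.599). SLC7A11, the cystine transporter, rose by 1.09 (SE 0.203, SD 0.559, n = 4 lines, adjusted p = 0.00914). SLC6A9, a glycine transporter, rose by 0.89 (SD 0.633, adjusted p = 0.0144) and MTHFD2, a mitochondrial folate enzyme, by 0.74 (SD 0.446, adjusted p = 0.00896). The integrated stress response list, which holds SLC7A11 and MTHFD2, was positive in 22 of 25 genes (median 0.305, adjusted p = 1.23e-05, and adjusted p = 0.503 with an estimated correlation). Both of these genes were called, and 6 when adjusted over the list alone. Its array medians were 0.58 in HBL1, 0.57 in TMD8, 0.22 in OCILY3 and -0.15 in OCILY10. HSPA1B and HSPA8, chaperones of the HSP70 family, fell by 0.87 (SD 0.391, adjusted p = 0.0326) and 0.72 (SD 0.444, adjusted p = 0.00383), although with median centring HSPA8 had 0.021. The heat shock list was negative in 15 of 17 (median -0.255, adjusted p = 1.23e-06, and 0.141 with an estimated correlation), with 4 called, 10 over the list alone. The cholesterol list was negative in 23 of 25 (median -0.22, adjusted p = 1.11e-05, and 0.599 with an estimated correlation), with NSDHL, an enzyme of sterol synthesis, at -0.37 (adjusted p = 0.0275). Its medians were -0.42 in HBL1 and -0.255 in TMD8 against -0.014 in OCILY3 and -0.061 in OCILY10. MYC targets and ribosome biogenesis genes were negative in 35 of 40 (median -0.20, adjusted p = 3.96e-09, and 0.107 with an estimated correlation). Of these 5 were called lower, such as RRS1 (-0.43), and 1 higher, FBL (0.43), and with 20 lower and 3 higher over the list alone.

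Other lists called at 2 h were the proteasome (median -0.092, 3 called lower, 9 over the list alone, adjusted p = 0.00032, and 0.107 with an estimated correlation), with PSMD11 at -0.40, and G1/S (-0.082, adjusted p = 0.00526, and 0.847 with an estimated correlation). So were glycolysis (-0.088, adjusted p = 0.00661, and 0.847 with an estimated correlation) and germinal centre genes (0.11, adjusted p = 0.0483, and 0.196). The glycolysis medians were -0.23 in HBL1 and -0.33 in TMD8 against 0.059 in OCILY3 and -0.012 in OCILY10. The germinal centre call was lost with the LogRatio deposited by the authors, and both calls were lost without the 3 bright arrays (adjusted p = 0.181 each). Further named genes were the B cell factor MEF2B (0.83), COL9A3 (0.80), RPLP0 (0.79), the calcium channel ITPR1 (0.76), ZBED3 (0.72) and the growth factor GRN (0.70) among the higher. LRFN4 (-0.66), FLAD1 (-0.65), SNORD86 (-0.62), FLNA (-0.61), PRR3 (-0.60), BDH1 (-0.60) and the cell cycle inhibitor CDKN1A (-0.57) were among the lower. In all 713 of 24437 genes were called at 2 h, 381 higher and 332 lower, but with the LogRatio deposited by the authors limma called 4 (3269 at an unadjusted p below 0.05). These were ATAD3C (-0.60), DHTKD1 (0.65), FLAD1 (-0.70) and an unnamed feature, XLOC_001124 (0.93), named here after their values were seen. Without HBL1, 59 genes were called, without TMD8 256, without OCILY3 262 and without OCILY10 174. There were, without the 3 bright arrays, 328 called genes, of which 233 were among the 713.

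At 4 h, the named genes that fell took in SRSF7, SRSF3, SRSF5 and SREK1, which act in splicing, a group that was not tested as such. They fell by 0.72 (SD 0.378, n = 4 lines, adjusted p = 0.0243), 0.57 (SD 0.29, adjusted p = 0.039), 0.48 and 0.475 (SD 0.221, adjusted p = 0.0199). NF-kB targets were negative in 36 of 40 with none called (median -0.19, adjusted p = 2.92e-07, and adjusted p = 0.571 with an estimated correlation), and none over the list alone. Examples are NFKB1 at -0.53 (SD 0.232, adjusted p = 0.168) and CD83 at -0.525. The proteasome list was negative in 27 of 31 (median -0.087, adjusted p = 5.87e-07), and its call held with an estimated correlation (adjusted p = 0.0135). PSMD11 (-0.35) was called, and 2 genes over the list alone. The integrated stress response list was the 1 list called higher (median 0.17, adjusted p = 0.00658, and 0.571 with an estimated correlation). Called lower were immediate early genes (-0.11, adjusted p = 0.000878, and 0.204 with an estimated correlation), G2/M (-0.099, 0.000878 and 0.576) and G1/S (-0.071, 0.00251 and 0.571). So were heat shock (-0.057, 0.00251 and 0.512) and ubiquitin genes (-0.087, 0.00297 and 0.512). Also called lower were interferon (-0.092, 0.00304 and 0.571), Toll-like receptor (-0.079, 0.00399 and 0.512) and cholesterol genes (-0.062, 0.00835 and 0.576). The last called lower were chemokine (-0.059, 0.0232 and 0.571), pro-death (-0.067, 0.03 and 0.571) and JAK-STAT3 genes (-0.098, 0.0335 and 0.571), with OCILY10 at -0.24 in the chemokine list against -0.044 to -0.006 in the other lines. With the LogRatio deposited by the authors the JAK-STAT3, pro-death and cholesterol calls were lost. Without the 3 bright arrays those were lost as well, as were the Toll-like receptor, interferon, immediate early, chemokine, heat shock and ubiquitin calls.

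The higher genes at 4 h were led by the ribosomal proteins RPL23 (0.93, SD 0.191, adjusted p = 4.01e-05), RPL41 (0.78), RPL13A (0.77), RPS18 (0.73) and RPS21 (0.69), with the histone H4C3 (0.73), SLC66A1 (0.73), ZNF865 (0.71) and GRN (0.69). Other lower genes were the ubiquitin ligase TRIM13 (-0.60), SERTAD1 (-0.52), C15orf39 (-0.51), FLVCR1 (-0.48), SCO1 (-0.47) and OXSR1 (-0.44). In all 233 genes were called, 189 higher and 44 lower, and limma called 0 with the LogRatio deposited by the authors (2048 at an unadjusted p below 0.05). Without OCILY10, 66 genes were called, without HBL1 107, without TMD8 114 and without OCILY3 155.

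At 6 h, the NF-kB and interferon lists were called lower, without a called member and without holding with an estimated correlation (adjusted p = 0.468 and 0.313), and OCILY3 had medians above 0 in both (0.072 and 0.053). NF-kB targets were negative in 38 of 40 with none called over all genes and 5 when adjusted over the list alone (median -0.27, adjusted p = 2.55e-10, and adjusted p = 0.468 with an estimated correlation). CD40, a receptor of the TNF family, stood at -0.76 (SD 0.79, n = 4 lines, adjusted p = 0.157) and NFKB2 at -0.50 (SD 0.441, adjusted p = 0.111). Type I interferon genes were negative in 35 of 40 with none called and 11 over the list alone (median -0.19, adjusted p = 6.69e-10, and 0.313 with an estimated correlation), such as USP18 at -0.66 (SD 0.576, adjusted p = 0.146). The interferon medians were -0.29 in HBL1, -0.445 in TMD8, -0.12 in OCILY10 and 0.053 in OCILY3. SAMD9L, an interferon-induced gene, fell by 0.67 (SD 0.451, adjusted p = 0.029) and JAK3, a cytokine receptor kinase, by 0.42 (SD 0.113, adjusted p = 0.0206), although JAK3 had 0.016 with median centring. Also called lower were the proteasome (-0.080, adjusted p = 0.000855, and 0.155 with an estimated correlation), and ubiquitin genes (-0.082, 0.00325 and 0.468). So were ABC subtype (-0.11, 0.0173 and 0.579), JAK-STAT3 (-0.17, 0.0269 and 0.579) and Toll-like receptor genes (-0.079, 0.0481 and 0.579). TMD8, a bright array at 6 h, had -0.34 in the ubiquitin list against -0.037 to -0.016 in the other lines, and OCILY3 had 0.11 in the JAK-STAT3 list. The JAK-STAT3 and Toll-like receptor calls were lost with the LogRatio deposited by the authors, and both of these, the ubiquitin and the ABC subtype calls without the 3 bright arrays. Higher genes were RPL13A (0.78, SD 0.056, adjusted p = 0.000169), RPLP0 (0.69), RPS16 (0.64), RPS2 (0.63), RPL23, RPS18, RPL41, H4C3 (0.64) and GRN (0.71). The other lower genes were KREMEN2 (-0.72), SNORA48 (-0.72), ELOA (-0.65), SPECC1 (-0.59), CCDC28B (-0.53), C15orf39 (-0.53), ARMC5 (-0.46) and ANP32D (-0.42, but 0.016 with median centring). In all 141 genes were called, 117 higher and 24 lower, and limma called 0 with the LogRatio deposited by the authors (2136 at an unadjusted p below 0.05) and 0 from the 4 arrays of that time alone (1712). Without HBL1, 34 genes were called, without OCILY10 39 and without TMD8 81.

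At 24 h, NF-kB targets were positive in 39 of 40 with none called over all genes or over the list alone (median 0.35, adjusted p = 5.39e-11, and adjusted p = 0.572 with an estimated correlation). IL10, a cytokine, stood at 0.69 (SD 0.502, n = 4 lines, adjusted p = 0.29), the inhibitor NFKBIA at 0.67 (SD 0.161, adjusted p = 0.299) and TRAF1 at 0.57 (SD 0.131, adjusted p = 0.227). H3C7, H3C10 and H3C8, each encoding histone H3, fell by 0.67 (SD 0.461, adjusted p = 0.0399), 0.64 (SD 0.47, adjusted p = 0.0466) and 0.62 (SD 0.399, adjusted p = 0.0145). NCAPD2, a condensin subunit, fell by 0.45 (SD 0.317, adjusted p = 0.0295). With median centring, which shifts all ratios, each of the 10 named lower genes at 24 h was above 0, from 0.005 for SCARNA22 to 0.53 for CDCA5. GPR183, a receptor that guides B cell migration, rose by 0.87 (SD 0.653, adjusted p = 0.0389), and HSPD1 and HSPE1, mitochondrial chaperones, rose by 0.38 and 0.37. MYC targets had a median of 0.049 with 4 called higher, 5 over the list alone (adjusted p = 0.000384, and 0.572 with an estimated correlation, as for each list called at 24 h). Oxidative phosphorylation (0.078, adjusted p = 0.00567), JAK-STAT3 (0.15, 0.0373), heat shock (0.062, 0.0428) and chemokine genes (0.080, 0.0479) were called higher. G2/M (-0.045, 0.00427), G1/S (-0.076, 0.0204) and the integrated stress response (-0.12, 0.0373) were called lower, and none of these 7 lists held with an estimated correlation (adjusted p = 0.572). TMD8 led several of these calls, with 0.33 in JAK-STAT3 against 0.023 to 0.075 in the other lines, and with -0.34 in G2/M, -0.31 in G1/S and -0.36 in the integrated stress response, where OCILY3 had 0.21, 0.086 and 0.041. In oxidative phosphorylation TMD8 had 0.16 against 0.002 in HBL1, 0.033 in OCILY3 and -0.027 in OCILY10. The G1/S, oxidative phosphorylation and heat shock calls were lost with the LogRatio deposited by the authors, and the heat shock and chemokine calls without the 3 bright arrays.

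Higher genes at 24 h also took in EEF1A1 (0.73), GRN (0.66), RPL41 (0.63), RPL13A (0.62), RPS16 (0.61), NPM1 (0.60), RPL7A (0.59) and RPL23 (0.565). The lower genes also took in SCARNA22 (-0.69), EIF3A (-0.47), LRWD1 (-0.37), CDCA5 (-0.36), XRCC1 (-0.35) and TM9SF4 (-0.35). In all 119 genes were called, 101 higher and 18 lower, and limma called 0 with the LogRatio deposited by the authors (2781 at an unadjusted p below 0.05) and 0 from the 4 arrays of that time alone (1809). Without OCILY10, 7 genes were called, without HBL1 13, without OCILY3 54 and without TMD8 63.

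Over the mean of the 4 times, ribosomal protein genes led the genes called above DMSO, in ratios that carry any dye bias and gave no called gene with the LogRatio deposited by the authors. RPL13A rose by 0.71 (SD 0.121, n = 4 lines, adjusted p = 0.00243), with RPL41 (0.67), RPL23 (0.66), RPLP0 (0.65), RPS18 (0.65), RPS16 (0.63), RPL7A (0.62), the elongation factor EEF1A1 (0.64) and GRN (0.69). Ribosomal proteins, a group chosen after the leading genes were seen, had 64 of 82 called higher, and 53 of 81 in the knockdown. At 2, 4, 6 and 24 h the counts called higher were 56, 64, 51 and 45. No test of the group is given, since it was picked for its place among the called genes. The mean of their array medians over the birinapant arrays was 0.405, but 0.095 with the LogRatio deposited by the authors and 1.25 with median centring. Other probes went the opposite way for EEF1A1 (-0.24), RPS2 (-0.31), NPM1 (-0.16) and RPS21 (-0.025 and -0.058). VASP, which binds actin filaments, fell by 0.46 (SD 0.036, adjusted p = 0.00243). C15orf39 (-0.49), SNORA48 (-0.50), SCARNA22 (-0.42), SNORA67 (-0.41), PRR3 (-0.40, another probe 0.013), SERTAD1 (-0.36), ELOA (-0.36, another probe 0.025), PYGB (-0.35) and ANKRD13D (-0.35) were also lower. With median centring each of these 10 genes was above 0, from 0.009 for SNORA48 to 0.161 for ELOA. Other probes of ZNF865 (-0.13), ARMC5 (0.012), MEF2B (-0.014), FLNA (0.011 and 0.042), NCAPD2 (0.081) and CDCA5 (0.007 and 0.039) also went against the probe used.

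Over the mean 10 lists were called, and none held with an estimated correlation (adjusted p = 0.836 for each). Lower lists were the proteasome (median -0.092, PSMD11 called at -0.32, 9 over the list alone, adjusted p = 0.000851), interferon (-0.040, 0.00246) and G1/S genes (-0.068, 0.00246), each with adjusted p = 0.836 with an estimated correlation. So were glycolysis (-0.061, 0.0179), ubiquitin (-0.058, 0.0179), cholesterol (-0.015, 0.042), Toll-like receptor (-0.049, 0.042), heat shock (-0.085, 0.042) and MYC target genes (-0.052, 0.0486). The integrated stress response was higher (0.080, 0.0486). Each of these also had adjusted p = 0.836 with an estimated correlation. The Toll-like receptor, G1/S, MYC target, integrated stress response, cholesterol and ubiquitin calls were lost with the LogRatio deposited by the authors. Of the 34 lists 4 were called with that LogRatio, 3 without the 3 bright arrays, 4 without HBL1 and 6 without TMD8. In all 484 genes were called, 329 higher and 155 lower, with limma calling 0 with that LogRatio (3614 at an unadjusted p below 0.05). Without HBL1, 75 genes were called, without OCILY10 82 and without TMD8 156. Without the 3 bright arrays it was 769, of which 390 were among the 484.

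Between 2 and 24 h of birinapant, the MYC target and heat shock lists were called higher and the integrated stress response list lower, the last of which did not hold with an estimated correlation (adjusted p = 0.343). MYC targets and ribosome biogenesis genes were positive in 36 of 40 (median 0.28, adjusted p = 3.78e-18) and heat shock genes in 15 of 17 (median 0.42, adjusted p = 9.04e-12), and both calls held with an estimated correlation (adjusted p = 0.0417 each). No member was called over all genes, and 17 and 12 were when adjusted over the list alone. Examples are HSPE1 (0.57), which is in both lists, the nucleolar gene NOLC1 (0.42) in the MYC list and DNAJA1 (0.62) in the heat shock list. The integrated stress response was negative in 24 of 25 (median -0.41, 3 over the list alone, adjusted p = 3.97e-10, and 0.343 with an estimated correlation). SLC7A11 stood at -1.02 and TRIB3 at -0.81. In OCILY10 its median went from -0.15 at 2 h to -0.067 at 24 h, opposite to the call. Cholesterol genes were positive in 21 of 25 (0.29, 3 over the list alone, adjusted p = 1.71e-06, and 0.533 with an estimated correlation), such as HMGCS1 at 0.64, with medians in TMD8 of -0.255 at 2 h and 0.40 at 24 h against -0.014 and -0.023 in OCILY3. NF-kB targets were positive in 34 of 40 (0.26, adjusted p = 2e-05, and 0.533 with an estimated correlation). Also called were the proteasome (0.11, 0.00566 and 0.253 with an estimated correlation), and oxidative phosphorylation (0.062, 0.00566 and 0.533). So were JAK-STAT3 (0.15, 0.00924 and 0.533), glycolysis (0.15, 0.00924 and 0.533) and G2/M, which was lower (-0.076, 0.00924 and 0.76). In OCILY3 the G2/M median went from 0.026 at 2 h to 0.21 at 24 h and the glycolysis median from 0.059 to -0.018, opposite to the calls and to the other lines. A test of whether a list's genes moved on balance one way (fry), which does not compare them with other genes, called MYC targets, heat shock and the proteasome. With the LogRatio deposited by the authors 7 of the 10 lists were called, glycolysis, oxidative phosphorylation and the proteasome being lost. Without TMD8, 6 lists were called, and without the 3 bright arrays the G2/M and glycolysis calls were lost.

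No single gene passed the threshold between 2 and 24 h: limma called 0 of 24437 (2389 at an unadjusted p below 0.05, smallest adjusted p = 0.116). Among the largest increases, which miss the threshold, were HSPA8 (0.92, SD 0.321, n = 4 lines, adjusted p = 0.116), GPR183 (0.84), HSPA1B (0.83) and the splicing factor SRSF2 (0.83, SD 0.365, adjusted p = 0.116). Among the largest decreases were CTH, an enzyme of cysteine synthesis (-1.18, SD 1.36, adjusted p = 0.419), MEF2B (-1.15), SLC7A11 (-1.02), HERPUD1 (-0.97), ZBED3 (-0.94) and FICD (-0.90). BIRC3 had 0.43 (adjusted p = 0.563), BIRC2 -0.044 and XIAP -0.16.

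Between 2 and 6 h, NF-kB targets went down in 38 of 40 genes (median -0.34, 6 over the list alone, adjusted p = 2.4e-10, and 0.397 with an estimated correlation). CD40 stood at -0.90 and RELB, an NF-kB subunit, at -0.83. Pro-survival genes were negative in 6 of 6 (median -0.30, 2 over the list alone, adjusted p = 0.00508, and 0.143 with an estimated correlation). BCL2A1 stood at -0.47 (SD 0.284) and CFLAR, an inhibitor of caspase 8, at -0.84 (another probe 0.17). Both, like BCL2L1, are also members of the NF-kB list, so the pro-survival and NF-kB calls are not independent. Interferon genes were lower (-0.30, adjusted p = 2.55e-08, and 0.397 with an estimated correlation), such as IFIH1, a sensor of viral RNA, at -0.91. The list median fell most in TMD8, from 0.34 at 2 h to -0.445 on its bright 6 h array, and rose in OCILY3 from 0.005 to 0.053. Also lower were the integrated stress response (-0.32, adjusted p = 3.1e-07, and 0.397 with an estimated correlation) and chemokines (-0.16, 0.012 and 0.474). In OCILY10 the stress response median went from -0.15 at 2 h to 0.008 at 6 h, opposite to the call. MYC targets (0.18, adjusted p = 3.21e-10, and 0.15 with an estimated correlation), and heat shock genes (0.28, 1.31e-09 and 0.102) were higher. So were cholesterol (0.25, 1.05e-05 and 0.531), G1/S (0.078, 0.019 and 0.596) and oxidative phosphorylation genes (0.041, 0.0471 and 0.596). The oxidative phosphorylation call was lost with the LogRatio deposited by the authors, and the pro-survival and G1/S calls without the 3 bright arrays. Of single genes limma called 0 of 24437 (2263 at an unadjusted p below 0.05, smallest adjusted p = 0.378). Among the largest values, which miss the threshold, were ND4L (0.77), HSPA8 (0.76, other probes -0.044 and -0.027), HSPA1B (0.73) and BDH1 (0.72). On the negative side they were SYNGR1 (-1.36), LHFPL6 (-1.18), ADAM8 (-1.13), SLC7A11 (-1.11, SD 0.771, adjusted p = 0.391) and IL4I1 (-1.10). BIRC3 had -0.36, BIRC2 -0.20 and XIAP -0.23.

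Between 6 and 24 h, a contrast added after the medians were seen, NF-kB targets went up in 40 of 40 genes, with none called over all genes and 33 when adjusted over the list alone (median 0.58, adjusted p = 2.83e-29, and adjusted p = 0.156 with an estimated correlation). IL10 stood at 0.99 and NFKB2 at 0.73. The list's median difference was 0.495 in HBL1, 0.833 in TMD8 and 0.861 in OCILY10, but 0.046 in OCILY3. JAK-STAT3 genes were higher (0.33, 6 over the list alone, adjusted p = 6.73e-06, and 0.229 with an estimated correlation). SOCS3, a feedback inhibitor, stood at 0.90 and STAT3 at 0.67 (SD 0.218, n = 4 lines, adjusted p = 0.137). In OCILY3 the JAK-STAT3 median went from 0.11 at 6 h to 0.053 at 24 h and the interferon median from 0.053 to -0.03, opposite to the calls. Interferon (0.19, 6.73e-06 and 0.32), chemokine (0.20, 0.000308 and 0.229), pro-survival (0.31, 0.00864 and 0.156), MYC target (0.082, 0.0087 and 0.439), ABC subtype (0.15, 0.0109 and 0.439) and Toll-like receptor genes (0.088, 0.0109 and 0.229) were higher. So were the TNF superfamily (0.057, 0.0258 and 0.229), ubiquitin (0.090, 0.0258 and 0.437), immediate early (0.082, 0.0265 and 0.32), proteasome (0.094, 0.0266 and 0.278) and non-canonical NF-kB genes (0.057, 0.0266 and 0.439), the second p in each case being that with an estimated correlation. The non-canonical NF-kB, proteasome and ubiquitin calls were lost with the LogRatio deposited by the authors, and the TNF superfamily, ABC subtype, immediate early, proteasome and ubiquitin calls without the 3 bright arrays. Several of the lists called between 6 and 24 h share members, so their calls are not independent. IL10 is in the NF-kB, JAK-STAT3 and chemokine lists, and CD40 in the NF-kB, non-canonical NF-kB and TNF superfamily lists. BIRC3 is in the non-canonical NF-kB and ubiquitin lists, and CXCL10 in the interferon and chemokine lists. STAT3 and BATF are also in more than 1 list. Of single genes limma called 0 (1721 at an unadjusted p below 0.05, smallest adjusted p = 0.137). Among the largest values of genes with 1 sign in every line, which miss the threshold, were BASP1 (1.45, SD 1.89), the adhesion receptor CD44 (1.36, SD 1.95), CT45A5 (1.32), CD40 (1.21, SD 0.648, adjusted p = 0.251) and CFLAR (1.21). On the negative side these took in LRRC2 (-1.09), RPA4 (-0.96), ND4L (-0.88), CHAC1 (-0.77) and ATP8 (-0.71). BIRC3 had 0.79 (SD 0.78, adjusted p = 0.621), BIRC2 0.16 and XIAP 0.069.

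The response of OCILY3 was set against that of the other 3 lines, which carry mutations of the B cell receptor subunits CD79A or CD79B. Over the mean of the 4 times, NF-kB targets were higher in OCILY3 in 30 of 40 genes, with none called over all genes or the list alone (median difference 0.16, adjusted p = 0.00141, and adjusted p = 0.894 with an estimated correlation). NFKBIA stood at 0.52 and TNFAIP3, a feedback inhibitor, at 0.30. The p53 list was also higher (17 of 26, median 0.087, adjusted p = 0.0191, and 0.894 with an estimated correlation), such as RRM2B at 0.365. Neither list was called with the LogRatio deposited by the authors (adjusted p = 0.229 each). Without TMD8, 10 lists were called. Of single genes 97 were called, 6 higher and 91 lower in OCILY3, from 1 line mean against 3, in a fit that assumes that the lone line varies like the others. With all 16 arrays and time as a block limma called 0 (2319 at an unadjusted p below 0.05). The higher genes were led by C9orf78 (0.91, SE 0.088, adjusted p = 0.02), AURKAP1 (0.86), MARCHF9 (0.79), RNASET2 (0.78) and CARS1, a cysteine tRNA ligase (0.63). The lower genes were led by SNORD105B (-1.01, adjusted p = 0.0234), SNORA26 (-0.98), RNA28SN5 (-0.97), KAT14 (-0.94), MBNL3 (-0.93), TCEA2 (-0.85), ZNF497 (-0.81), RABGAP1 (-0.80), BTBD1 (-0.76) and SEMA4A (-0.73). BIRC2 (0.10), BIRC3 (0.24) and XIAP (0.18) were not called. With the LogRatio deposited by the authors limma called 0 genes (2351 at an unadjusted p below 0.05), without HBL1 0 (1241), without TMD8 148 and without OCILY10 222. Across the 4 lines at once limma called 0 genes (1668 at an unadjusted p below 0.05, smallest adjusted p = 0.465).

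The responses to knockdown and drug were compared across genes in HBL1 and TMD8. Genes are not independent replicates, so the correlation carries no p-value. At 24 h the mean responses correlated weakly over 14502 genes (Pearson r = 0.148, Spearman rho = 0.177, and r = 0.126 without ribosomal proteins). Line by line, the 24 h response correlated with the knockdown of the same line at 0.309 in HBL1 and -0.008 in TMD8, and with that of the other line at 0.205 and 0.08. The pooled r was 0.304 without the TMD8 array, 0.056 with the authors' value table and 0.64 with median centring. For the change from 2 to 24 h r was -0.033 (rho = -0.026, 14177 genes), and for the mean of 4 and 6 h r was 0.117 (rho = 0.07, 14247 genes). Of 92 genes called at 24 h and measured in both, 88 had the same sign in the knockdown, against 8140 of all 14502, in ratios that share the dye order. In the change from 2 to 24 h, a dye bias common to all arrays cancels on the drug side. There 403 of 786 genes called in the knockdown had the same sign, against 6971 of all 14177. NF-kB targets were lower in the knockdown of 3 and 4 days (median -0.16). With birinapant their medians at 4, 6 and 24 h were -0.33, -0.33 and 0.12 in HBL1 and -0.14, -0.16 and 0.63 in TMD8. The sign was thus that of the knockdown at 4 and 6 h and the opposite at 24 h, which was not tested.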

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

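The tests of the intensity trend, of handling or time in culture and of other splits were chosen before their results were seen, and the others below were chosen only after the result was seen. Of 78 groups of 4 arrays tested, 13 held an array far from the other 3, where chance gives about 1 in 20 groups. Lists entered these groups only where camera had called them.

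Brightness set 3 arrays apart. HBL1 at 2 h had 69.8% of probes above background in Cy3 against 35.3% to 41.1% on the other arrays of that time, and 83% against 40.5% to 45.4% in Cy5. HBL1 at 4 h had 81.8% in Cy3 against 41.6% to 42.8%, and 85.1% in Cy5 against 41.2% to 44.3%. TMD8 at 6 h had 92.4% in Cy3 against 41.2% to 43.5%, and 95.6% in Cy5 against 43.3% to 45.6%. On that array XIAP stood at -0.903 against 0.0293 to 0.193, and the linear and K63 ubiquitin list at -0.341 against -0.037 to -0.016.

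Among the called lists, other arrays stood apart in 1 list each. At 2 h the germinal centre median of TMD8 was 0.035 against 0.116 to 0.131, and the proteasome median of OCILY3 was -0.106 against -0.081 to -0.076. At 4 h the chemokine median of OCILY10 was -0.236 against -0.044 to -0.006. The JAK-STAT3 median of OCILY3 at 6 h was 0.108 against -0.225 to -0.188, and that of TMD8 at 24 h was 0.332 against 0.023 to 0.075. Uncalled lists were not checked. In some of them the TMD8 knockdown array at 3 days lay far from the others. It had -0.207 against 0.142 to 0.177 in the integrated stress response and 0.296 against -0.035 to -0.009 for chemokines. For immediate early genes it had 0.313 against -0.17 to -0.096.

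Groups were also called different from each other. For OCILY3, 1 line set against 3, 97 genes were called, as were the NF-kB targets (adjusted p = 0.00141; 30 of 40 genes higher) and the p53 list (adjusted p = 0.0191; 17 of 26 higher). Both lists had adjusted p = 0.894 with an estimated correlation, no gene was called by limma with all 16 arrays (2319 at an unadjusted p below 0.05), and no list or gene was called with the deposited LogRatio. Between times, 10 lists were called for 24 against 2 h, 10 for 6 against 2 h and 13 for 24 against 6 h, of which 2, 0 and 0 held with an estimated correlation. In the knockdown the arrays of TMD8 and HBL1 had opposite signs in 5 lists, a difference that was not tested: TMD8 minus HBL1 was 0.186 for JAK-STAT3, 0.186 for p53, 0.321 for G1/S, 0.236 for cholesterol and 0.044 for the ubiquitin list.

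Ribosomal protein genes read above the control on each birinapant array (mean of the array medians 0.405, SD 0.065). A response that follows exposure time was argued against, since the median moved by -0.032 (SD 0.079) from 2 to 24 h. Dye bias may contribute and cannot be told apart from a shared response, because the knockdown arrays, with the same dye order, gave 0.959 of the birinapant value. An intensity trend left by the normalization stays open as a part of it, because other genes of matched intensity had 0.159 (SD 0.052). Whether such a trend is the whole cause could not be decided by a test set after these values were seen. Ribosomal genes exceeded the matched genes by 0.246 (SD 0.042) and, with the deposited LogRatio, by 0.072 (SD 0.038) on 16 of 16 arrays. But the group was picked for its place among the genes called higher, which makes an excess likely from the choice alone.

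NF-kB targets stood below DMSO at 4 and 6 h and above it at 24 h in HBL1, TMD8 and OCILY10. On the other 4 arrays of these lines at 4 and 6 h, which were not bright, the highest median was -0.135. The 24 h values exceeded those at 6 h by at least 0.495 in each of the 3 lines. OCILY3, which shares its row and columns with HBL1 (-0.333 and -0.329), had -0.001 as the lower of its medians at 4 and 6 h. The pattern was drawn up from these medians, so the values restate it and are no test of bright arrays, dye bias or slide position. They do show that the fall was not confined to the bright arrays and that the ratios were not constant over time. A response that depends on the line stays open and was not tested: 97.5% of the list's genes were higher in OCILY3 at 4 and 6 h, but the pattern was drawn up without OCILY3 because its medians had been seen, so this share restates it. Handling or time in culture was not tested for this list.

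From 2 to 24 h MYC targets and heat shock genes went up in most lines. The bright arrays were argued against, since the MYC difference without HBL1 was 0.9 of that over 4 lines. Handling or time in culture cannot be told apart from the drug, because the DMSO label has no time: the DMSO channel shifted by -0.032 (SD 0.034), which decides nothing if the arrays of a line share a DMSO sample. Chance could not be excluded for the number of genes at an unadjusted p below 0.05: between 24 and 2 h 3 of 35 splits of the arrays gave as many as the real 2389 (highest other 2855), and between 6 and 2 h 7 of 35 gave as many as 2263 (highest other 4294). Of the 8 splits that part each line's pair, the real one alone reached its count between 24 and 2 h (highest other 1963) and 5 did between 6 and 2 h (highest other 2949), and for differences among lines 16 of 100 shuffles reached 1668 (highest other 4513), so chance could not be excluded there either.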

How the results depend on the processing

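Calls against DMSO depended on the normalization, list calls on the correlation assumed, and most counts on single lines; of the alternatives for counts, correlations and list counts 121 stayed near their value and 90 moved. The runs without the 3 bright arrays and the list tests with the block exchanged were chosen after seeing the data, and the cause was not tested unless stated. Dim probes limited the genes tested, with 35.3% to 47.7% of probes above background on most birinapant arrays. Aquantile leaves log ratios unchanged by construction. No alternative gave a call between 24 and 2 h or 6 and 2 h, where limma called 0 with and without the replicate block.

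For 2, 4, 6 and 24 h, the mean, OCILY3, differences among lines and the knockdown, LogRatio gave 4, 0, 0, 0, 0, 0, 1 (GRXCR1, named after its value was seen) and 103 calls (81 higher, 22 lower), with 3269, 2048, 2136, 2781, 3614, 2351, 1580 and 3879 at an unadjusted p below 0.05. The value table gave 11, 0, 0, 0, 0, 0, 1 (GRXCR1 as well) and 94 (76 higher, 18 lower), with 3531, 1961, 2036, 2692, 3721, 2462, 1831 and 3926 unadjusted. Median centring, with which the median of all genes stood at 0.207 on average (0.005 otherwise), gave 3788 (3666 higher, 122 lower), 151 (all higher), 265 (all higher), 8523 (8468 and 55), 10103 (10080 and 23), 2843 (2726 and 117), 37 and 8111 (7915 and 196).

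The arrays of each time alone gave 111, 101, 0 and 0 calls (1712 and 1809 unadjusted at 6 and 24 h), with fewer residual degrees of freedom. Slide 1 gave 0 (3000 unadjusted), 0 (1254), 4, 0 (956) and, for the mean, 2154; slide 2 gave 0 (2959), 1, 0 (1736), 1 and 126, each from 2 lines. Chosen after their values were seen, these were SYNGR1 (-3.35) and 3 unnamed features at 6 h, RPL23 (0.88) at 4 h and LOC440292 (1.16) at 24 h. For the mean, a slide block gave 1657, the stricter filter 740, an intensity trend 757, and leaving out the bright arrays 769 (2 h: 328). OCILY3 had 13 with the stricter filter and 0 with all 16 arrays (2319 unadjusted).

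With the line as a replicate block the knockdown had 2726 calls, with a random block 589 and with line means 0 (2736 unadjusted); at 2, 4, 6 and 24 h the fixed block gave 695, 245, 151 and 135 and the random block 722, 237, 140 and 121. The block added 2 lists in the knockdown (12) and, when removed, left 10 between 24 and 2 h; no other list comparison was run with the block exchanged. Apart from the knockdown it moved no count of called genes by over 1.5 times. Leaving out a line gave 59 to 262 (2 h), 66 to 155 (4 h), 34 to 138 (6 h), 7 to 63 (24 h), 75 to 347 (mean), 0 to 222 (OCILY3) and 0 to 586 (knockdown arrays) calls; the lowest came without HBL1, except at 4 and 24 h without OCILY10, and in the knockdown without HBL1 at 3 days (3451 unadjusted). The correlation was 0.039 to 0.304 (without TMD8), and 0.64 with median centring.

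For lists over the mean, between 24 and 2 h, in OCILY3 and in the knockdown, an estimated correlation gave 0, 2, 0 and 0 calls, fry 0, 3, 0 and 4, and LogRatio 4, 7, 0 and 9; leaving out the bright arrays gave 3, 8 and 2. Leaving out a line or array gave 4 (HBL1) to 10, 6 (TMD8) to 10, 3 to 10 (TMD8) and 11 to 13.

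Of values for named genes 2123 stayed, 892 lost and 5 gained their call, 27 uncalled changed sign and 23 called reversed, each with median centring, which shifts all ratios. These were HSPA8 at 2 h (0.021), ANP32D and JAK3 at 6 h (0.016 each), and at 24 h SCARNA22 (0.005), H3C7 (0.162), H3C10 (0.108), H3C8 (0.214), EIF3A (0.453), NCAPD2 (0.402), LRWD1 (0.417), CDCA5 (0.53), XRCC1 (0.452) and TM9SF4 (0.341). Over the mean they were SNORA48 (0.009), C15orf39 (0.024), VASP (0.076), SCARNA22 (0.103), SNORA67 (0.11), PRR3 (0.031), SERTAD1 (0.156), ELOA (0.161), PYGB (0.145) and ANKRD13D (0.152).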

Other observations

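Some called genes went against or beside their list. In the knockdown, NRF2 targets moved both ways: GCLC, which makes glutathione, was higher (0.31, SD 0.101, n = 4 arrays, adjusted p = 0.037), and ABCC1, an export pump, was lower (-0.26, SD 0.042, adjusted p = 0.0388), as was FTH1, the ferritin heavy chain (-0.29, adjusted p = 0.0488). TNFRSF13B, a receptor for B cell survival factors, fell by 0.50 (SD 0.244, adjusted p = 0.0347), the B cell coactivator POU2AF1 by 0.39 (SD 0.173, adjusted p = 0.0384), the cytokine subunit IL23A by 0.36 (adjusted p = 0.031) and SREBF2, a regulator of sterol genes, by 0.30 (SD 0.099, adjusted p = 0.0416). Among the reference genes ACTB was higher (0.60, SD 0.157, adjusted p = 0.0109) and PGK1, an enzyme of glycolysis, lower (-0.25, SD 0.049, adjusted p = 0.0486).

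At 2 h of birinapant the chaperones PDIA4 and DNAJB11 of the endoplasmic reticulum were lower by test (-0.49, SD 0.297, n = 4 lines, adjusted p = 0.0156, and -0.27, SD 0.106, adjusted p = 0.0193). FTH1 was higher (0.46, SD 0.205, adjusted p = 0.016), as was DDB2, a DNA repair gene induced by p53 (0.49, SD 0.349, adjusted p = 0.0245), while the p53 target CDKN1A was lower (-0.57). The mitotic genes CDC20 (-0.37, adjusted p = 0.0178) and UBE2C (-0.34, adjusted p = 0.0314) were lower and ASPM, also mitotic, higher (0.34, adjusted p = 0.0437). Over the mean of the 4 times the survival gene BCL2 was higher (0.36, SD 0.145, adjusted p = 0.0285; another probe -0.078) and BST2, an interferon-induced gene, lower (-0.33, SD 0.09, adjusted p = 0.0161). These are members of the lists with the smallest p, and like the other ratios against DMSO they carry any dye bias.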
